A study of Homo sapiens with 24 samples.

How the data were processed

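Transcript levels were measured by RNA sequencing in MCF7 cells and a TP53 knockout line, with 3 libraries per group at days 0, 3, 14 and 21 of 50 nM abemaciclib. The deposited files hold raw counts per Ensembl gene. Per the labels the authors trimmed reads with Trimmomatic 0.36, aligned them to GRCh38 with STAR 2.5.2b and made the counts with featureCounts, Subread 1.5.2. The strand setting, the treatment of reads with several positions and the annotation release are not stated. Gene names and biotypes came from the local GRCh38 annotation, which held 56410 of the 57500 gene identifiers. Total counts per library lay between 15260609 and 36558260. The labels call day 0 DMSO and the series description calls it no treatment. Day 1 of the series design is not analysed here.

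Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 8 groups, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 24 libraries, leaving 16 residual degrees of freedom. The 16 contrasts compared p53KO with parental at each day, each later day with day 0 in each line, day 21 with day 3 in each line, and the differences between the lines in these changes. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 20248 genes of each contrast, with a threshold of 0.05. An exact test of 3 against 3 libraries cannot go below 0.1, so tests rest on the model that pools the spread over genes. CPM values use the TMM-scaled library sizes.

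Lists of genes were fixed before the data were examined, 25 in all: p53 target genes, DNA replication and S phase genes, mitosis genes, homologous recombination and fork protection genes, replication-dependent histone genes, cyclin D, CDK and RB family genes, senescence-associated secretory genes, interferon-stimulated genes, MHC class I antigen presentation genes, estrogen receptor target genes, luminal epithelial genes, basal and mesenchymal genes, cholesterol synthesis genes, lysosome and autophagy genes, hypoxia and glycolysis genes, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded genes, ribosome biogenesis and MYC-linked genes, unfolded protein and ATF4 response genes, AP-1 and immediate early genes, BCL2 family and caspase genes, fibroblast markers, leukocyte and blood markers, endothelial markers and reference genes. Each was tested in each contrast with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 25 lists of a contrast. An estimated correlation was the alternative. Counts adjusted over the list alone use the gene p-values of edgeR.

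The genes named followed a rule fixed beforehand. It took the 5 protein-coding genes with the largest fold in each direction (3 where contrasts are described together) among those called, with mean log2 CPM of at least 1 and groups that do not overlap (a condition not set for differences between the lines in a change), the 2 members with the smallest adjusted p in each direction of each list described, and 44 fixed genes, of which 1 was not tested. Examples were drawn from these. Members of a list counted 5 or fewer were named after their values were seen, as were IGF2 and AFP as foreign markers.

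The alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, the replicate number as a block, only the compared groups in the fit, each replicate left out in turn, and the estimated correlation. The ones added afterwards left out 6 libraries with foreign transcripts (which leaves 1 library of p53KO at day 0, its spread taken from the other groups), left out 2 libraries short of long transcripts, or exchanged the day 0 baselines. Foreign transcripts were counted where the summed CPM of a marker list was at least 5 times the lowest replicate and at least 50. Replicate numbers did not pair libraries across groups.

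The steps were tested on simulated day 14 data with known folds between the lines. Gene tests recovered 35 of 67 genes changed 1.5-fold, 51 of 67 2-fold and 61 of 66 4-fold. Of 20023 unchanged genes 13 were called, 7.26% of 179 calls. A list given a 1.5-fold shift was called and 0 of the lists sharing no gene with it were. Neither tests the preset correlation, and both hold for the simulated spread, which real libraries need not share. Tables and plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.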

Results

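RNA was sequenced from MCF7 cells, an established estrogen receptor positive breast cancer line, and from a TP53 knockout line made from them with Cas9 and named p53KO. Both lines were grown in 50 nM abemaciclib, an inhibitor of the cyclin D-dependent kinases CDK4 and CDK6, and collected at days 0, 3, 14 and 21. The 8 groups held 3 libraries each. The comparisons address changes over weeks in the drug and differences between the lines. No other knockout clone or Cas9 control is labelled, so p53KO differences need not stem from TP53 loss. Of 57500 genes, 20248 had enough counts to be tested. Log2 fold changes are given with their standard error and levels as mean CPM ± SD, CPM being counts scaled to a common library size, with n = 3 libraries per group throughout, and a change was called at adjusted p below 0.05 with edgeR. The labels do not say whether the 3 replicates were separate cultures, so the p-values measure only the spread between these libraries. Positions are on GRCh38.

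The targeted gene kept its transcript in the knockout line. TP53 (ENSG00000141510, chromosome 17, 7661779 to 7687550) stood at 104 ± 3.26 CPM in p53KO cells and 120.1 ± 1.51 in parental cells at day 3, at 114 ± 10.5 and 79.6 ± 8.17 at day 14, and at 50.6 ± 2.82 and 18.1 ± 0.341 at day 21. The libraries labelled p53KO and parental at day 0 held 158 ± 11.9 and 145 ± 3.8. Its log2 fold change between the lines was 1.48 ± 0.09 (adjusted p = 7e-13) at day 21. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), the p53 target that encodes a cyclin-dependent kinase inhibitor, separated them at the treated times: 384 ± 28.1 CPM in parental against 157 ± 8.42 in p53KO cells at day 3, 263 ± 33.4 against 207 ± 9.35 at day 14, and 297 ± 9.72 against 84.1 ± 2.75 at day 21. At day 0 the order was the other way round, with 102 ± 8.18 in the libraries labelled parental and 245 ± 24.4 in those labelled p53KO.

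**Figure D1:**
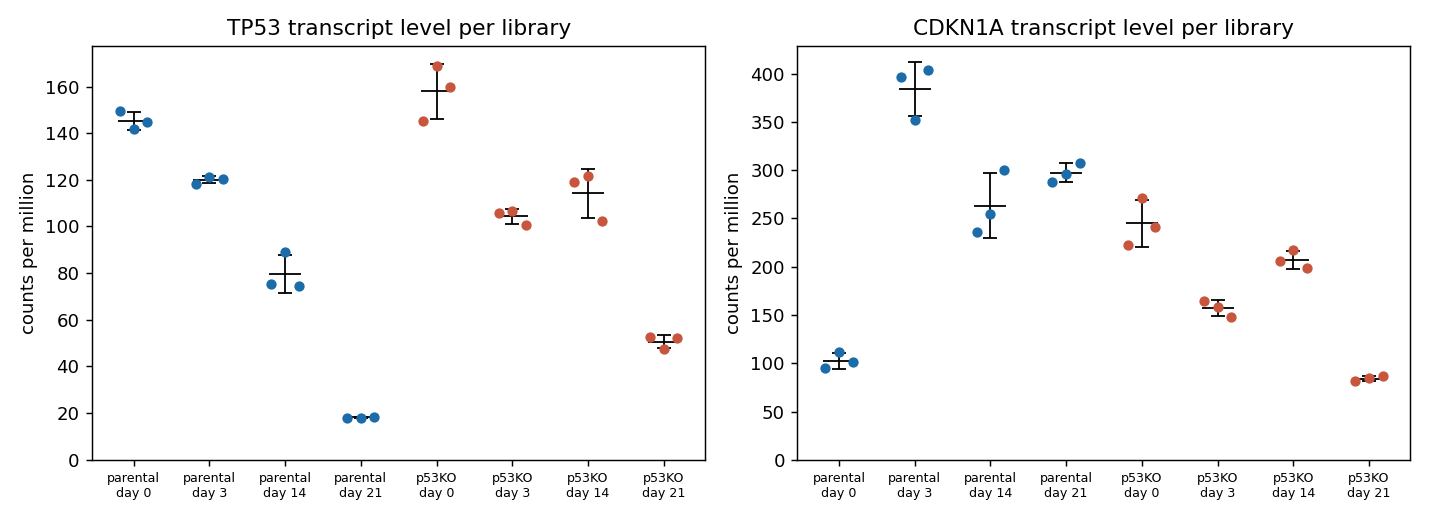
Transcript level of TP53 and CDKN1A in CPM in each of the 24 libraries, by group; points are libraries, horizontal marks the group means and whiskers 1 SD (n = 3), blue for parental and red for p53KO. TP53 falls to 18.1 ± 0.341 in parental cells at day 21, and CDKN1A is higher in parental than in p53KO libraries at days 3, 14 and 21 and lower at day 0.

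Some libraries differed from their replicates. Summed transcripts of 20 fetal liver and mesenchyme markers, among them IGF2 and AFP, reached 2820.0 CPM in p53KO day 14 replicate 3, 2341 in p53KO day 0 replicate 1, 998 in parental day 14 replicate 1 and 505 in parental day 3 replicate 2. At equal totals these 4 libraries held a count for 20958, 20937, 20279 and 22894 genes in that order, and the other replicates of their groups for 24501 to 26545. Heart muscle markers summed to 102 CPM in p53KO day 0 replicate 3 and 94.5 in p53KO day 21 replicate 2. Long transcripts were low in parental day 14 replicate 3 and parental day 0 replicate 2, with slopes of -0.303 and -0.176 log2 units per doubling of length. Mitochondrially encoded transcripts took 14.1 ± 0.433% of the counts in parental cells at day 21, 8.33 ± 0.548% at day 3 and 7.46 ± 0.27% in p53KO cells at day 21.

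**Figure D2:**
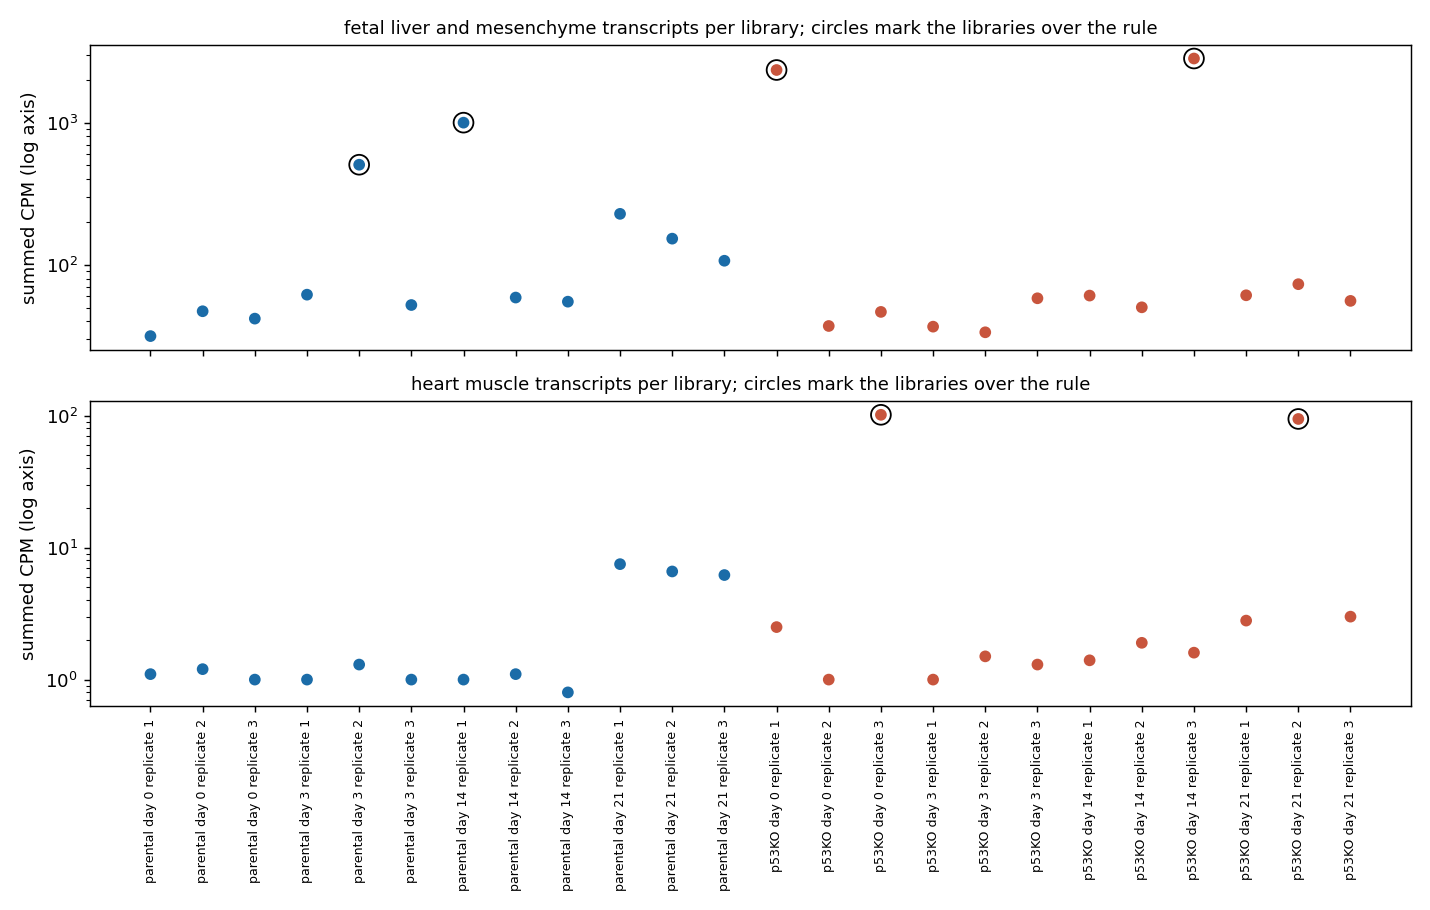
Summed CPM, on log axes, of fetal liver and mesenchyme markers (20 genes) and heart muscle markers (10 genes) in each library, blue for parental and red for p53KO; circles mark libraries at least 5 times the lowest of their group and over 50 CPM. The 4 circled libraries of the upper panel lie between 505 and 2820.0 CPM.

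After 3 days of abemaciclib interferon-stimulated genes were higher in p53KO than in parental cells. Interferon-induced transcripts that were near absent in parental cells were abundant in p53KO cells: XAF1 (ENSG00000132530, chromosome 17, 6755447 to 6775647) stood at 91.4 ± 0.643 CPM against 0.434 ± 0.115, and IFIT1 (ENSG00000185745, chromosome 10, 89392546 to 89406486) at 325 ± 14.8 against 4 ± 0.932. The largest log2 fold changes upward were XAF1 7.69 ± 0.24, OAS2 6.65 ± 0.18, IFIT1 6.34 ± 0.15, IFI44L 6.32 ± 0.24 and IFI27 6.25 ± 0.28, all interferon-induced. The largest downward were SLC17A9 (ENSG00000101194, chromosome 20, 62952647 to 62969585), a vesicular nucleotide transporter, at -5.34 ± 0.24, the potassium channel subunit KCNE4 at -4.17 ± 0.23, the receptor ERBB4 at -3.94 ± 0.36, the protease inhibitor CSTA at -3.87 ± 0.21 and the kinase TNIK at -3.56 ± 0.20. Over all genes 2827 were higher and 2577 lower in p53KO, 1047 and 569 of them by 2-fold or more. With only the 6 libraries compared in the fit the counts were 4336 and 3953.

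Among the 37 interferon-stimulated genes tested at day 3, 36 were higher, 0 were lower and 1 did not pass (36 and 0 adjusted over the list alone). Their median was 4.56 and camera gave adjusted p = 4.6e-55. IFIT3 changed by 6.06 ± 0.14 (adjusted p = 1e-19). The 18 MHC class I antigen presentation genes followed: 16 were higher, 1 was lower (PDIA3) and 1 did not pass (16 and 1 adjusted over the list alone). Their median was 2.19 and camera gave adjusted p = 1.3e-14. Examples were the peptide transporters TAP1 at 3.07 ± 0.17 and TAP2 at 2.68 ± 0.13. Of the 44 p53 target genes, 4 were higher (FBXW7, ASCC3, DRAM1, TRIM22), 18 were lower and 22 did not pass (4 and 18 adjusted over the list alone). Their median was -0.28 and camera gave adjusted p = 9.6e-06. The stress cytokine GDF15 changed by -2.52 ± 0.16 and CDKN1A by -1.29 ± 0.09, while TRIM22, a p53 target that interferon also induces, was among the higher members at 6.32 ± 0.75. Lysosome and autophagy genes were lower as a group: 2 were higher (ATP6V1A, UVRAG), 21 were lower and 18 did not pass (2 and 22 adjusted over the list alone). Their median was -0.30 and camera gave adjusted p = 2e-06, or adjusted p = 0.058 with an estimated correlation. Examples were CTSB at -1.06 ± 0.08 and GLA at -1.53 ± 0.12. For the 13 mitochondrially encoded genes, 0 were higher, 12 were lower and 1 did not pass (0 and 12 adjusted over the list alone). Their median was -0.68 and camera gave adjusted p = 2.2e-09, or adjusted p = 0.058 with an estimated correlation. MT-ND4 changed by -0.85 ± 0.08. Of 21 luminal epithelial genes, 2 were higher (ESR1, AR), 13 were lower and 6 did not pass (2 and 14 adjusted over the list alone). Their median was -0.41 and camera gave adjusted p = 1e-05, or adjusted p = 0.058 with an estimated correlation. SPDEF, a luminal transcription factor, changed by -1.91 ± 0.14 and XBP1 by -0.96 ± 0.10.

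Cell cycle genes at day 3 hinged on 1 parental library. Of 44 mitosis genes, 1 was higher (NDC80), 21 were lower and 22 did not pass (1 and 29 adjusted over the list alone). Their median was -0.77 and camera gave adjusted p = 0.00011, or adjusted p = 0.57 with an estimated correlation. AURKA changed by -0.64 ± 0.11 and PRC1 by -0.92 ± 0.16. Parental day 3 replicate 2, which held the fetal liver transcripts, had the highest mitosis gene level of the 3 parental libraries, and MKI67 averaged 38.4 ± 27.2 CPM in that group. Without this library the mitosis list gave adjusted p = 0.25 (range over its alternatives 3.6e-08 to 0.57). Of 44 DNA replication and S phase genes, 4 were higher (MCM3, POLA1, SLBP, DNMT1), 4 were lower (RFC2, PRIM1, RRM2, E2F8) and 36 did not pass (4 and 4 adjusted over the list alone). Their median was -0.12 and camera gave adjusted p = 0.47, which did not pass. The direction turned without that library, with adjusted p = 0.22 (range over its alternatives 0.056 to 0.84).

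By day 14 MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385), the standard marker of cycling cells, stood at 94.6 ± 8.29 CPM in p53KO and 3.36 ± 1.01 in parental cells, a log2 fold change of 4.80 ± 0.36 (adjusted p = 3.1e-10). TOP2A stood at 95.7 ± 11.7 against 12.1 ± 2.54 and CCNB1, the mitotic cyclin B, at 72.6 ± 0.286 against 39.7 ± 1.68. Of 44 mitosis genes, 43 were higher, 0 were lower and 1 did not pass (43 and 0 adjusted over the list alone). Their median was 2.91 and camera gave adjusted p = 3.7e-29, or adjusted p = 0.057 with an estimated correlation. The kinesin KIFC1 changed by 2.89 ± 0.19 and CDC20, an activator of the anaphase-promoting complex, by 2.94 ± 0.20. Of 44 DNA replication and S phase genes, 39 were higher, 0 were lower and 5 did not pass (40 and 0 adjusted over the list alone). Their median was 0.79 and camera gave adjusted p = 2.5e-15, or adjusted p = 0.099 with an estimated correlation. Examples were UHRF1 at 2.82 ± 0.23 and thymidine kinase TK1 at 3.46 ± 0.29. For the 20 homologous recombination and fork protection genes, 15 were higher, 0 were lower and 5 did not pass (16 and 0 adjusted over the list alone). Their median was 1.21 and camera gave adjusted p = 1.3e-06, or adjusted p = 0.2 with an estimated correlation. RAD54L changed by 2.32 ± 0.24 and RMI2 by 1.32 ± 0.14. CCNE2 was higher by 2.36 ± 0.28, FOXM1 by 3.23 ± 0.39, MYBL2 by 3.74 ± 0.37 and E2F1 by 0.57 ± 0.18. The E2F1 call ended without parental day 14 replicate 2 and with only these 6 libraries in the fit.

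The interferon difference was still present at day 14. Of 37 interferon-stimulated genes, 36 were higher, 0 were lower and 1 did not pass (36 and 0 adjusted over the list alone). Their median was 3.25 and camera gave adjusted p = 5.6e-32. Examples were LGALS3BP at 3.25 ± 0.09 and HERC6 at 4.20 ± 0.13. Among the 18 MHC class I genes, 15 were higher, 0 were lower and 3 did not pass (16 and 1 adjusted over the list alone). Their median was 2.15 and camera gave adjusted p = 1.7e-11. HLA-B changed by 3.39 ± 0.19 and HLA-C by 2.22 ± 0.13. Of the p53 target genes, 9 were higher, 15 were lower and 20 did not pass (10 and 16 adjusted over the list alone). Their median was -0.18 and camera gave adjusted p = 0.011. The lower ones included DRAM1 at -1.47 ± 0.08 and PERP at -1.21 ± 0.09, both linked to cell death. Lysosome and autophagy genes were again lower: 2 were higher (GAA, UVRAG), 28 were lower and 11 did not pass (2 and 28 adjusted over the list alone). Their median was -0.54 and camera gave adjusted p = 3.1e-11. Examples were CD63 at -1.84 ± 0.13 and CTSB at -1.10 ± 0.08. The largest changes upward were XAF1 6.06 ± 0.22, the reductase AKR1B10 5.90 ± 0.32, UBA7, the enzyme that activates ISG15, 5.39 ± 0.28, OAS2 5.38 ± 0.18 and the scaffold gene IQGAP3 5.04 ± 0.40. Downward they were SLC17A9 -4.87 ± 0.23, WNT2B -4.52 ± 0.22, KCNE4 -3.69 ± 0.22, HCK -3.37 ± 0.34 and ERBB4 -3.20 ± 0.34. Over all genes 3890 were higher and 3415 lower in p53KO, 1616 and 1058 by 2-fold or more. With only these 6 libraries in the fit the counts were 1462 and 1559; each group held 1 library with fetal liver transcripts, and the parental group 1 short of long transcripts.

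**Figure D3:**
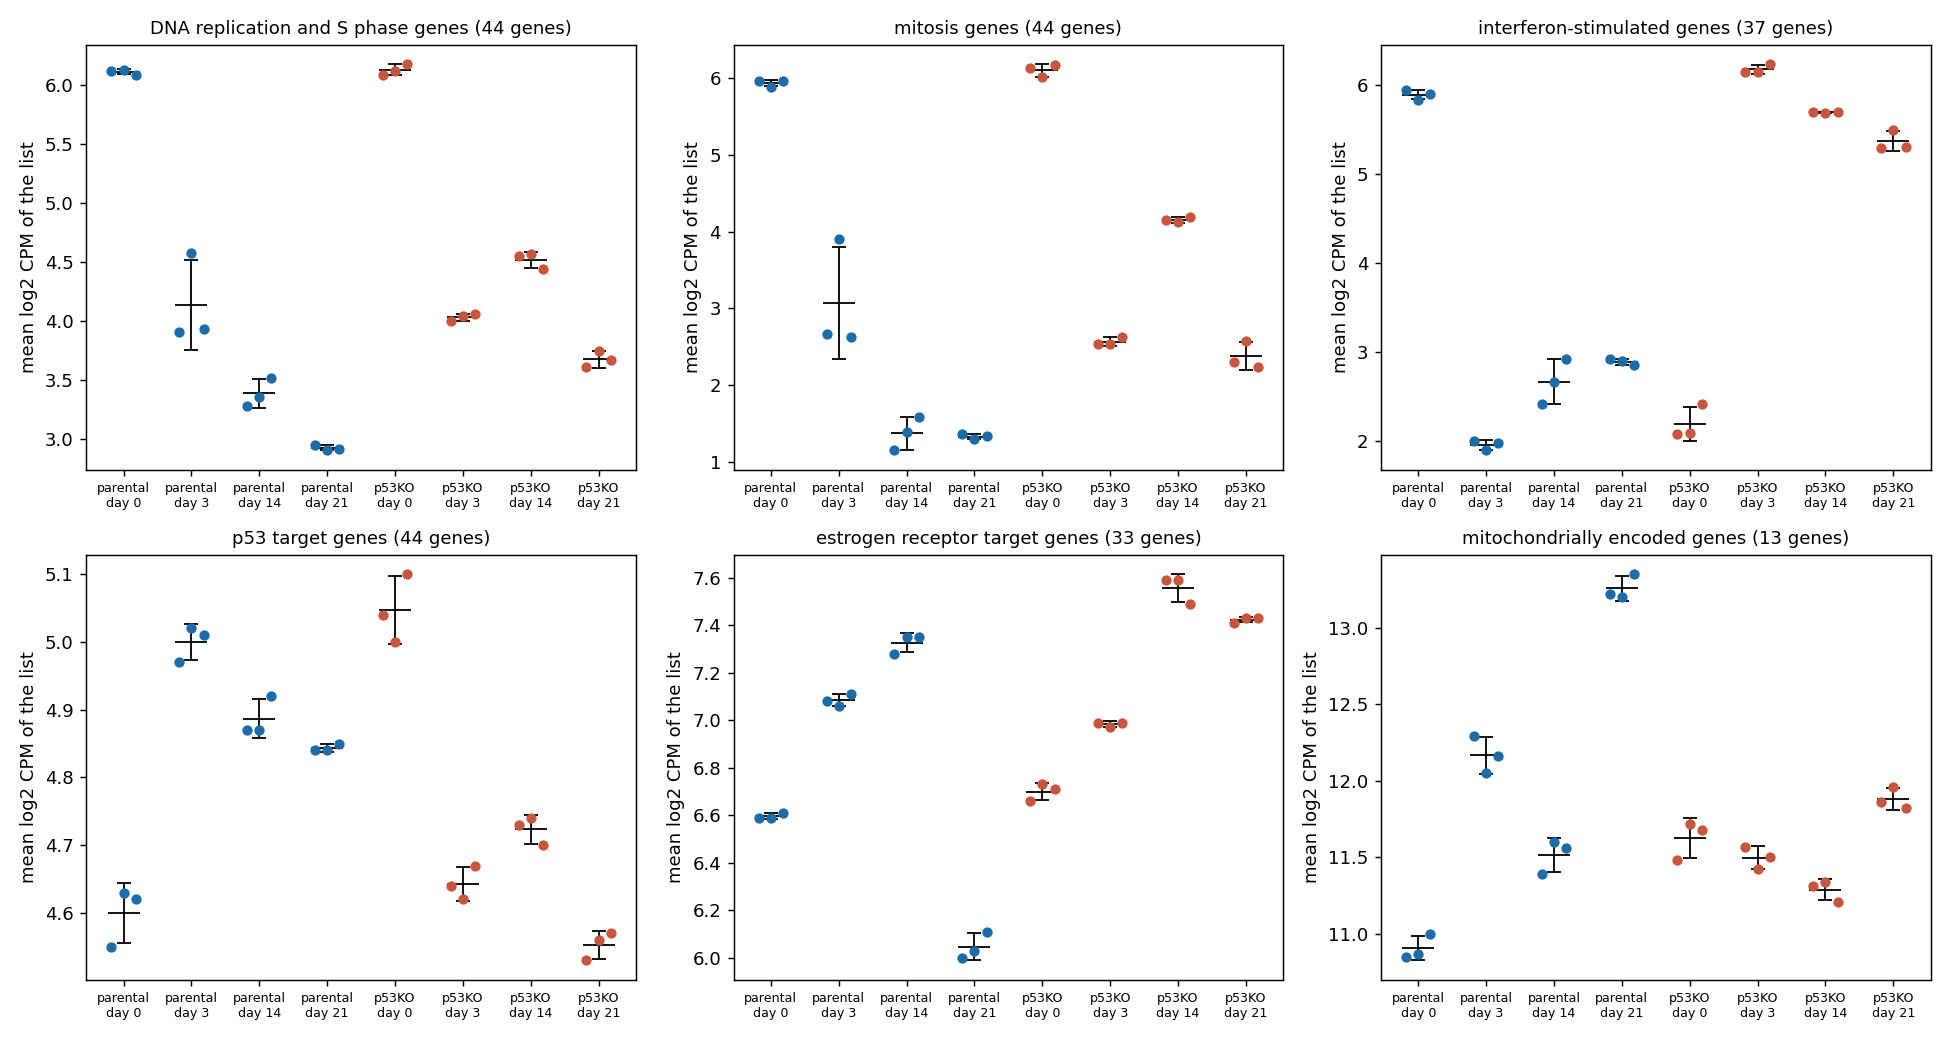
Mean log2 CPM of 6 gene lists in each library, by group; points are libraries, horizontal marks the group means and whiskers 1 SD (n = 3), blue for parental and red for p53KO, and the vertical axes do not start at 0. The mitosis list stands at 4.15 ± 0.04 in p53KO and 1.37 ± 0.22 in parental cells at day 14, and the estrogen receptor target list at 7.42 ± 0.01 and 6.05 ± 0.06 at day 21.

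At day 21 the lines had moved far apart, with 6536 genes higher and 5966 lower in p53KO, 3824 and 3539 by 2-fold or more. With DESeq2 size factors the majority turned, with 5720 higher and 6856 lower. CCND1 (ENSG00000110092, chromosome 11, 69641087 to 69654474), which encodes the cyclin D partner of the drug's target kinases, stood at 650.3 ± 20.2 CPM in p53KO and 61.3 ± 1.78 in parental cells, a log2 fold change of 3.41 ± 0.09 (adjusted p = 2.6e-18). Estrogen-responsive genes went the same way: PGR, the progesterone receptor, differed by 3.22 ± 0.14, GREB1 by 3.26 ± 0.15 and ESR1, the estrogen receptor itself, by 1.83 ± 0.13. Of 33 estrogen receptor target genes, 23 were higher, 5 were lower (CTSD, TPD52L1, RERG, KCNK5, MREG) and 5 did not pass (24 and 6 adjusted over the list alone). Their median was 1.31 and camera gave adjusted p = 6.9e-07. The fatty acid elongase ELOVL2 changed by 3.55 ± 0.10 and PDZK1 by 3.34 ± 0.09. Of 28 cyclin D, CDK and RB family genes, 20 were higher, 5 were lower (CCNE2, CDKN1A, CDKN1C, CDKN2D, E2F4) and 3 did not pass (20 and 5 adjusted over the list alone). Their median was 0.72 and camera gave adjusted p = 0.0062, or adjusted p = 0.25 with an estimated correlation. For mitosis genes, 30 were higher, 3 were lower (PLK1, CENPA, INCENP) and 11 did not pass (31 and 3 adjusted over the list alone). Their median was 1.36 and camera gave adjusted p = 0.00065, or adjusted p = 0.64 with an estimated correlation. MKI67 stood at 12.8 ± 1.85 against 4.25 ± 0.645 CPM. For DNA replication and S phase genes, 30 were higher, 4 were lower (MCM10, FEN1, SLBP, E2F2) and 10 did not pass (31 and 4 adjusted over the list alone). Their median was 0.77 and camera gave adjusted p = 0.00026, or adjusted p = 0.45 with an estimated correlation. MCM3 and MCM5 of the replicative helicase changed by 1.91 ± 0.08 and 2.06 ± 0.11.

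Interferon-stimulated genes were higher at day 21 as well: 34 were higher, 0 were lower and 3 did not pass (34 and 0 adjusted over the list alone). Their median was 2.65 and camera gave adjusted p = 2.7e-12. An example was the transcription factor STAT1 at 3.10 ± 0.09. Of the MHC class I genes, 14 were higher, 2 were lower (TAPBP, CALR) and 2 did not pass (14 and 2 adjusted over the list alone). Their median was 1.00 and camera gave adjusted p = 0.016, or adjusted p = 0.4 with an estimated correlation. The p53 target genes went both ways: 11 were higher, 21 were lower and 12 did not pass (11 and 21 adjusted over the list alone). Their median was -0.19 and camera gave adjusted p = 0.092, which did not pass. GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176) changed by -4.09 ± 0.17 (adjusted p = 7.2e-16) and CDKN1A by -1.82 ± 0.09, while BTG2 and PLK2 changed by 2.12 ± 0.09 and 1.67 ± 0.07. Mitochondrially encoded genes were lower: 0 were higher, 13 were lower and 0 did not pass (0 and 13 adjusted over the list alone). Their median was -1.35 and camera gave adjusted p = 2.4e-07, or adjusted p = 0.17 with an estimated correlation. An example was MT-ND2 at -2.44 ± 0.09. Leukocyte and blood markers stood at a mean log2 CPM of 1.21 ± 0.09 in the parental and -0.50 ± 0.48 in the p53KO libraries, and endothelial markers at 0.25 ± 0.31 and -1.26 ± 0.48. Of the lysosome and autophagy genes, 10 were higher, 26 were lower and 5 did not pass (10 and 26 adjusted over the list alone). Their median was -0.72 and camera gave adjusted p = 0.00065, or adjusted p = 0.25 with an estimated correlation. The lysosomal channel MCOLN1 changed by -2.72 ± 0.11. The largest changes upward were ZNF385B 4.72 ± 0.27, OPN3 4.65 ± 0.26, NHS 4.57 ± 0.32, A2M 4.53 ± 0.63 and DACH1 4.40 ± 0.34. Downward they were PRSS35 (ENSG00000146250, chromosome 6, 83512538 to 83525704) at -7.14 ± 0.58, with 972 ± 33.2 CPM in parental and 6.89 ± 0.57 in p53KO cells, CUZD1 at -5.39 ± 0.30, the arginase ARG2 at -5.12 ± 0.27, LSMEM1 at -5.05 ± 0.15 and NFKBIZ, a nuclear regulator of NF-kappaB, at -5.01 ± 0.16. With DESeq2 size factors the median log2 fold change of all genes was -0.12 here, 0.19 for parental cells from day 3 to day 21 and 0.22 for them from day 0 to day 21. It was -0.15 and -0.13 for the difference between the lines in the change to day 21 from day 0 and from day 3, and changes in these comparisons are relative to it.

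Part of the difference between the lines was common to the 3 treated times. 1097 genes were higher in p53KO at days 3, 14 and 21, where 175.3 were expected if the calls were independent, and 770 were lower, where 128.1 were expected. At 2-fold or more the counts were 379 higher, against 15.8 expected, and 99 lower, against 5.2. Of the 44 p53 target genes, 7 were lower and 2 higher at all 3 times.

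Between day 3 and day 21 parental cells changed in most of their measured genes: 6661 genes rose and 6808 fell, 4646 and 4013 by 2-fold or more. More genes rose than fell with DESeq2 size factors, 7676 and 5733. At equal totals the 3 parental libraries of day 21 held a count for 34, 38 and 42 of 376 olfactory receptor genes, those of p53KO for 27, 28 and 26, and the earlier parental libraries for 5 to 16. The nuclear transcript MALAT1 took 1.41 ± 0.134% of the counts in parental cells at day 21 and 0.392 ± 0.024% at day 3. Members of 2 marker lists of other cell types rose too. A marker low in all other groups could enter the test only through parental day 21, and one low everywhere did not enter. That selection favours rises in the counts and in camera for these lists. Of 7 leukocyte and blood markers, 5 rose (CD79A, CD14, LYZ, ITGAM, SPI1), 0 fell and 2 did not pass (5 and 0 adjusted over the list alone). Their median was 2.90 and camera gave adjusted p = 0.046, or adjusted p = 0.34 with an estimated correlation. Their mean log2 CPM was 1.21 ± 0.09 at day 21 and -1.64 ± 0.13 at day 3. Of 5 endothelial markers, 3 rose (PECAM1, VWF, EMCN), 0 fell and 2 did not pass (3 and 0 adjusted over the list alone). Their median was 0.87 and camera gave adjusted p = 0.34, which did not pass. Their mean log2 CPM was 0.25 ± 0.31 and -1.20 ± 0.29. CCND1 dropped from 876 ± 35.1 to 61.3 ± 1.78 CPM, a log2 fold change of -3.84 ± 0.09 (adjusted p = 7.3e-20). MYC changed by -2.53 ± 0.09 and ESR1 by -1.95 ± 0.13. Transcripts barely present at day 3 became abundant, among them EDNRB (ENSG00000136160, chromosome 13, 77895481 to 77919768), an endothelin receptor, from 0.357 ± 0.144 to 351 ± 6.57 CPM, a log2 fold change of 9.90 ± 0.53. The other largest rises were the transporter SLC6A12 9.83 ± 0.65, PRSS35 9.45 ± 0.68, the steroid-metabolising AKR1C1 8.99 ± 0.51 and the cytochrome CYP3A5 8.16 ± 0.35. The largest falls were HCK -5.07 ± 0.44, KIF12 -4.97 ± 0.20, MPP2 -4.81 ± 0.29, SPDEF -4.77 ± 0.17 and PMP22 -4.76 ± 0.19.

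Cell cycle lists fell further in parental cells after day 3: of DNA replication and S phase genes, 4 rose (MCM10, FEN1, SLBP, E2F2), 35 fell and 5 did not pass (4 and 35 adjusted over the list alone). Their median was -1.36 and camera gave adjusted p = 3e-06, or adjusted p = 0.37 with an estimated correlation. Of mitosis genes, 2 rose (CENPA, INCENP), 41 fell and 1 did not pass (2 and 42 adjusted over the list alone). Their median was -2.13 and camera gave adjusted p = 3e-06, or adjusted p = 0.38 with an estimated correlation. TOP2A changed by -3.11 ± 0.27 and MCM4 by -2.49 ± 0.09. Estrogen receptor target genes fell: 7 rose, 23 fell and 3 did not pass (8 and 23 adjusted over the list alone). Their median was -1.11 and camera gave adjusted p = 0.00019, or adjusted p = 0.08 with an estimated correlation. CA12 changed by -3.13 ± 0.07 and RET by -3.53 ± 0.11. Luminal epithelial genes fell as well: 3 rose (ELF3, CLDN4, PRLR), 17 fell and 1 did not pass (3 and 17 adjusted over the list alone). Their median was -1.53 and camera gave adjusted p = 0.00019, or adjusted p = 0.25 with an estimated correlation. CDH1, the epithelial cadherin, changed by -1.78 ± 0.09. In the cyclin D, CDK and RB family, 3 rose (CDK6, CDKN2D, E2F4), 19 fell and 6 did not pass (4 and 19 adjusted over the list alone). Their median was -0.84 and camera gave adjusted p = 0.00061, or adjusted p = 0.25 with an estimated correlation. Mitochondrially encoded genes rose: 13 rose, 0 fell and 0 did not pass (13 and 0 adjusted over the list alone). Their median was 1.08 and camera gave adjusted p = 0.00014, or adjusted p = 0.33 with an estimated correlation. An example was MT-ND2 at 2.30 ± 0.09. Of the lysosome and autophagy genes, 29 rose, 7 fell and 5 did not pass (29 and 7 adjusted over the list alone). Their median was 0.84 and camera gave adjusted p = 0.00064, or adjusted p = 0.33 with an estimated correlation. Examples were MCOLN1 at 3.36 ± 0.12 and NPC2 at 2.84 ± 0.13. Senescence-associated secretory genes were mixed: 14 rose, 4 fell (IGFBP4, TIMP2, AREG, TGFB1) and 11 did not pass (14 and 4 adjusted over the list alone). Their median was 1.33 and camera gave adjusted p = 0.036, or adjusted p = 0.41 with an estimated correlation. Examples were VEGFA at 5.89 ± 0.17 and ICAM1 at 4.66 ± 0.20. Of the interferon-stimulated genes, 21 rose, 5 fell (STAT1, STAT2, BST2, PARP9, LGALS3BP) and 11 did not pass (21 and 5 adjusted over the list alone). Their median was 0.97 and camera gave adjusted p = 0.018, or adjusted p = 0.33 with an estimated correlation. With DESeq2 size factors the secretory list gave adjusted p = 0.062 (range over its alternatives 0.011 to 0.41).

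In p53KO cells the same interval brought fewer calls: 2389 genes rose and 3345 fell, 1080 and 522 by 2-fold or more. At equal totals olfactory receptor genes with a count numbered 10, 15 and 13 in the day 3 libraries and 27, 28 and 26 in those of day 21. MALAT1 took 0.341 ± 0.043% of the counts at day 3 and 0.549 ± 0.103% at day 21, and NEAT1, also nuclear, 0.056 ± 0.001% and 0.197 ± 0.019%. The library p53KO day 21 replicate 2 held the heart muscle transcripts. The largest rises were OLFML3 5.46 ± 0.54, the kallikrein KLK11 4.61 ± 0.15, SGPP1 4.39 ± 0.34, the protease inhibitors A2M 4.31 ± 0.61 and SERPINA1 4.15 ± 0.16, and the largest falls NDC80 -3.19 ± 0.20, MFAP2 -2.77 ± 0.32, RASGRP1 -2.71 ± 0.16, TEX19 -2.53 ± 0.26 and PADI2 -2.45 ± 0.32. Interferon-stimulated genes fell: 0 rose, 27 fell and 10 did not pass (0 and 29 adjusted over the list alone). Their median was -0.95 and camera gave adjusted p = 4.6e-11. Examples were OAS2 at -2.09 ± 0.13 and LGALS3BP at -1.30 ± 0.09. Estrogen receptor target genes rose: 16 rose, 3 fell (MYB, FHL2, MREG) and 14 did not pass (19 and 3 adjusted over the list alone). Their median was 0.34 and camera gave adjusted p = 5.4e-05. Examples were STC2 at 1.55 ± 0.09 and KCNK5 at 2.44 ± 0.15. Lysosome and autophagy genes rose: 24 rose, 3 fell (GLA, GAA, GLB1) and 14 did not pass (27 and 3 adjusted over the list alone). Their median was 0.36 and camera gave adjusted p = 8.1e-08, or adjusted p = 0.053 with an estimated correlation. Examples were GUSB, beta-glucuronidase, at 2.49 ± 0.09 and GPNMB at 3.59 ± 0.28. Nuclear-encoded oxidative phosphorylation genes fell: 0 rose, 17 fell and 10 did not pass (0 and 18 adjusted over the list alone). Their median was -0.47 and camera gave adjusted p = 1.4e-06, or adjusted p = 0.32 with an estimated correlation. An example was UQCRC2 at -0.68 ± 0.08. Of DNA replication and S phase genes, 2 rose (CDC6, TYMS), 21 fell and 21 did not pass (2 and 21 adjusted over the list alone). Their median was -0.36 and camera gave adjusted p = 5.4e-05, or adjusted p = 0.38 with an estimated correlation. Of mitosis genes, 1 rose (INCENP), 4 fell (MKI67, MYBL2, PRC1, NDC80) and 39 did not pass (1 and 3 adjusted over the list alone). Their median was -0.21 and camera gave adjusted p = 0.43, which did not pass, and without the libraries with foreign transcripts camera gave adjusted p = 0.013 (range over its alternatives 0.013 to 0.87). MKI67 lost its call without any 1 of these 6 libraries. With only these 6 libraries in the fit, 5029 genes rose and 5065 fell.

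The change from day 3 to day 21 differed between the lines for 9309 genes, 5067 with a higher log2 fold change in p53KO and 4242 with a lower one. The majority turned with DESeq2 size factors, with 4291 higher and 5054 lower. CCND1 was higher by 3.16 ± 0.12 (adjusted p = 1.5e-15) and MYC by 2.13 ± 0.12 in the p53KO change. The largest differences upward were SFXN2 4.73 ± 0.18, EPHA3 4.62 ± 0.42, DACH1 4.52 ± 0.46, C6orf141 4.32 ± 0.15 and TENM4 4.29 ± 0.35, and downward PRSS35 -9.50 ± 0.84, TNFAIP3 -7.76 ± 0.44, AKR1C1 -7.15 ± 0.58, ARG2 -6.41 ± 0.41 and SLC6A12 -6.39 ± 0.76. Of the estrogen receptor target genes, 24 had a higher change, 3 had a lower one (FHL2, RERG, KCNK5) and 6 did not pass (24 and 3 adjusted over the list alone). Their median was 1.59 and camera gave adjusted p = 2e-09. CA12 differed by 3.04 ± 0.10. Of the interferon-stimulated genes, 1 had a higher change (STAT2), 27 had a lower one and 9 did not pass (1 and 29 adjusted over the list alone). Their median was -2.08 and camera gave adjusted p = 7.1e-09. IFIT3 differed by -3.53 ± 0.17. Mitosis genes went with the estrogen list: 37 had a higher change, 2 had a lower one (CENPA, INCENP) and 5 did not pass (37 and 2 adjusted over the list alone). Their median was 1.98 and camera gave adjusted p = 1.9e-06, or adjusted p = 0.45 with an estimated correlation. So did DNA replication and S phase genes, where 28 had a higher change, 3 had a lower one (MCM10, SLBP, E2F2) and 13 did not pass (31 and 3 adjusted over the list alone). Their median was 1.06 and camera gave adjusted p = 2.4e-05, or adjusted p = 0.4 with an estimated correlation. Of luminal genes, 14 had a higher change, 3 had a lower one (ELF3, CLDN4, PRLR) and 4 did not pass (15 and 3 adjusted over the list alone). Their median was 1.00 and camera gave adjusted p = 0.00027, or adjusted p = 0.24 with an estimated correlation. Among MHC class I genes, 1 had a higher change (PDIA3), 14 had a lower one and 3 did not pass (1 and 14 adjusted over the list alone). Their median was -1.16 and camera gave adjusted p = 0.00062, or adjusted p = 0.27 with an estimated correlation.

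Proliferation genes were lower after abemaciclib than at day 0 in both lines, whichever day 0 libraries served as the baseline; none of the 24 libraries is a vehicle control of the later times. MKI67 stood at 275 ± 86.9 CPM in the libraries labelled parental at day 0 and at 38.4 ± 27.2, 3.36 ± 1.01 and 4.25 ± 0.645 at days 3, 14 and 21. In p53KO it stood at 439 ± 27.1 in the day 0 libraries and at 22.5 ± 1.39, 94.6 ± 8.29 and 12.8 ± 1.85 later. In parental cells, of the 44 DNA replication and S phase genes at day 3, 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -1.79 and camera gave adjusted p = 1.3e-32. At day 14, 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -2.22 and camera gave adjusted p = 4.1e-30. At day 21, 1 rose (E2F2), 43 fell and 0 did not pass (1 and 43 adjusted over the list alone). Their median was -3.20 and camera gave adjusted p = 3.7e-17, or adjusted p = 0.095 with an estimated correlation. Of the mitosis genes at day 3, 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -2.83 and camera gave adjusted p = 3.9e-31. At day 14, 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -4.80 and camera gave adjusted p = 2.4e-32. At day 21, 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -4.96 and camera gave adjusted p = 3.7e-17, or adjusted p = 0.12 with an estimated correlation. KIFC1 changed by -3.07 ± 0.17, -4.73 ± 0.20 and -5.40 ± 0.21. The homologous recombination list fell in parental cells at day 3, where 0 rose, 20 fell and 0 did not pass (0 and 20 adjusted over the list alone). Their median was -2.01 and camera gave adjusted p = 7.7e-15. At day 14, 0 rose, 20 fell and 0 did not pass (0 and 20 adjusted over the list alone). Their median was -2.56 and camera gave adjusted p = 1e-13. At day 21, 0 rose, 19 fell and 1 did not pass (0 and 19 adjusted over the list alone). Their median was -3.62 and camera gave adjusted p = 7.6e-09, or adjusted p = 0.11 with an estimated correlation.

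In p53KO cells DNA replication and S phase genes fell at day 3, where 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -2.01 and camera gave adjusted p = 2.8e-31. At day 14, 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -1.57 and camera gave adjusted p = 4.3e-23. At day 21, 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -2.21 and camera gave adjusted p = 1e-25. Mitosis genes fell at day 3, where 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -3.64 and camera gave adjusted p = 2.8e-34. At day 14, 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -1.96 and camera gave adjusted p = 1.1e-18, or adjusted p = 0.11 with an estimated correlation. At day 21, 0 rose, 44 fell and 0 did not pass (0 and 44 adjusted over the list alone). Their median was -3.85 and camera gave adjusted p = 1e-25, or adjusted p = 0.059 with an estimated correlation. PRC1 changed by -3.65 ± 0.17, -2.46 ± 0.16 and -4.18 ± 0.18. Estrogen receptor target genes rose at day 14 in both lines: in parental cells 22 rose, 4 fell (PDZK1, SIAH2, FHL2, EGR3) and 7 did not pass (23 and 4 adjusted over the list alone). Their median was 0.57 and camera gave adjusted p = 8.7e-07. In p53KO cells 21 rose, 5 fell (CXCL12, XBP1, CA12, SLC39A6, KCNK5) and 7 did not pass (21 and 5 adjusted over the list alone). Their median was 0.91 and camera gave adjusted p = 2.4e-06. PGR changed by 3.27 ± 0.13 in p53KO, or 2.08 with the day 0 baselines exchanged. In the same setting, in parental cells at day 14 PDZK1 stood at 0.76 (adjusted p = 1.3e-07), SIAH2 stood at -0.16 (adjusted p = 0.18), FHL2 stood at -0.43 (adjusted p = 0.12) and EGR3 stood at 0.30 (adjusted p = 0.089). In p53KO cells XBP1 stood at -0.32 (adjusted p = 0.012), CA12 stood at 0.46 (adjusted p = 8.7e-06), SLC39A6 stood at 0.63 (adjusted p = 4.9e-07) and KCNK5 stood at 0.74 (adjusted p = 0.0004). Lysosome and autophagy genes rose in parental cells at day 3, where 32 rose, 0 fell and 9 did not pass (32 and 0 adjusted over the list alone). Their median was 0.63 and camera gave adjusted p = 1.5e-14. At day 14, 34 rose, 2 fell (GLA, GAA) and 5 did not pass (35 and 2 adjusted over the list alone). Their median was 0.90 and camera gave adjusted p = 3.8e-14. At day 21, 33 rose, 4 fell (GLA, GAA, LIPA, GLB1) and 4 did not pass (33 and 4 adjusted over the list alone). Their median was 1.34 and camera gave adjusted p = 4.4e-09, or adjusted p = 0.052 with an estimated correlation. LIPA lost its call there with the baselines exchanged, standing at -0.14. GNS changed by 1.58 ± 0.10 at day 3, or 0.91 with the baselines exchanged.

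Over all genes, in parental cells 3432 genes rose and 4024 fell at day 3, 4536 and 4896 at day 14, and 6863 and 7108 at day 21. In p53KO cells the counts were 4059 and 4358, 4366 and 4657, and 5169 and 5721. More genes rose than fell with DESeq2 size factors at days 14 and 21 in parental cells, 4846 and 4550 and 7902 and 5999, and at each time in p53KO cells, 4319 and 4064, 4526 and 4454 and 5737 and 5114. The largest changes in parental cells as labelled were, at day 3, ERBB4 5.09 ± 0.41, SLC17A9 4.56 ± 0.22 and KCNE4 4.34 ± 0.24 upward and XAF1 -6.44 ± 0.24, OAS2 -6.28 ± 0.18 and IFI44L -5.97 ± 0.24 downward. Against the other day 0 libraries these 6 genes stood at -0.26, 0.36, 0.03, -0.56, -0.01 and -0.60. At day 14 they were NOS3 5.96 ± 0.22, CAPN8 5.53 ± 0.26 and SHC2 5.31 ± 0.31 upward and DLGAP5 -6.61 ± 0.37, FAM111B -6.57 ± 0.49 and MCM10 -6.47 ± 0.35 downward, or 5.42, 4.84, 2.49, -6.54, -6.44 and -6.33 against the other day 0 libraries. At day 21 they were PRSS35 8.83 ± 0.65, MYRFL 8.57 ± 0.31 and CYP3A5 8.37 ± 0.36 upward and HJURP -6.55 ± 0.35, MYBL2 -6.43 ± 0.39 and PTTG1 -6.26 ± 0.46 downward, or 7.12, 6.40, 6.95, -6.50, -6.01 and -6.56 against the other day 0 libraries. The largest changes in p53KO cells as labelled were, at day 3, XAF1 7.13 ± 0.23, IFI27 6.65 ± 0.29 and OAS2 6.64 ± 0.18 upward and PIF1 -5.56 ± 0.47, PBK -5.26 ± 0.38 and SLC17A9 -4.98 ± 0.24 downward. Against the other day 0 libraries these 6 genes stood at 1.25, 0.33, 0.37, -4.14, -4.75 and -0.78. At day 14 they were AKR1B10 6.77 ± 0.35, KLK11 6.61 ± 0.19 and XAF1 6.48 ± 0.23 upward and SLC17A9 -4.80 ± 0.23, ERBB4 -3.84 ± 0.34 and FBXO17 -3.83 ± 0.29 downward, or 0.40, 4.95, 0.60, -0.61, 1.51 and -1.39 against the other day 0 libraries. At day 21 they were KLK11 7.12 ± 0.19, AKR1B10 6.53 ± 0.35 and XAF1 6.04 ± 0.23 upward and PIF1 -5.23 ± 0.45, MYBL2 -5.15 ± 0.36 and PBK -5.14 ± 0.37 downward, or 5.46, 0.16, 0.15, -3.80, -5.57 and -4.63 against the other day 0 libraries. Against the day 0 libraries of the other label, 2071 genes rose and 2479 fell in parental cells at day 3.

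Most calls of interferon-stimulated and p53 target genes against day 0 ended or turned with the day 0 baselines exchanged; the rise of interferon-stimulated genes in p53KO cells at day 3 kept its direction and call. As labelled, interferon-stimulated genes fell in parental cells at day 3, where 0 rose, 35 fell and 2 did not pass (0 and 35 adjusted over the list alone). Their median was -4.36 and camera gave adjusted p = 4.1e-37. They rose in p53KO cells, where 36 rose, 0 fell and 1 did not pass (36 and 0 adjusted over the list alone). Their median was 4.19 and camera gave adjusted p = 1.1e-34. Against the day 0 libraries of the other label the parental fall gave adjusted p = 0.23 and the p53KO rise adjusted p = 0.011 (range over its alternatives 9.1e-38 to 0.011). At day 14 as labelled they fell in parental cells, where 1 rose (ISG20), 34 fell and 2 did not pass (1 and 34 adjusted over the list alone). Their median was -3.62 and camera gave adjusted p = 9.3e-23. They rose in p53KO cells, where 36 rose, 0 fell and 1 did not pass (36 and 0 adjusted over the list alone). Their median was 3.60 and camera gave adjusted p = 8.6e-30. With the baselines exchanged both directions turned, with adjusted p = 0.0039 and 0.18. Of the p53 target genes as labelled at day 3, in parental cells 21 rose, 9 fell and 14 did not pass (21 and 9 adjusted over the list alone). Their median was 0.24 and camera gave adjusted p = 0.00067. In p53KO cells 8 rose, 25 fell and 11 did not pass (8 and 26 adjusted over the list alone). Their median was -0.39 and camera gave adjusted p = 0.0019. With the baselines exchanged the calls ended, with adjusted p = 0.9 in parental cells and, with the direction turned, 0.74 in p53KO cells.

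The later times went the same way as labelled. At day 21 interferon-stimulated genes were lower than at day 0 in parental cells, where 0 rose, 34 fell and 3 did not pass (0 and 34 adjusted over the list alone). Their median was -3.55 and camera gave adjusted p = 6e-12. They were higher in p53KO cells, where 34 rose, 0 fell and 3 did not pass (34 and 0 adjusted over the list alone). Their median was 3.28 and camera gave adjusted p = 1.6e-20. Exchanged baselines turned both directions, with adjusted p = 0.099 and 0.00076. Of the p53 target genes at day 14, in parental cells 21 rose, 14 fell and 9 did not pass (21 and 14 adjusted over the list alone). Their median was 0.28 and camera gave adjusted p = 0.021. In p53KO cells 8 rose, 23 fell and 13 did not pass (8 and 24 adjusted over the list alone). Their median was -0.24 and camera gave adjusted p = 0.0061. Without the libraries with foreign transcripts the parental list at day 14 gave adjusted p = 0.063. At day 21 the p53 list in parental cells had members on both sides: 20 rose, 17 fell and 7 did not pass (22 and 17 adjusted over the list alone). Their median was 0.22 and camera gave adjusted p = 0.52, which did not pass. In p53KO cells at day 21, 10 rose, 26 fell and 8 did not pass (11 and 29 adjusted over the list alone). Their median was -0.63 and camera gave adjusted p = 0.0012. With the baselines exchanged the p53 list gave adjusted p = 0.76 and 0.42 at day 14 and 0.42 and 0.37 at day 21.

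Interferon-stimulated genes were lower and p53 target genes higher in the libraries labelled p53KO at day 0 than in those labelled parental, the opposite of day 3. 2752 genes were higher and 2509 lower in those labelled p53KO, 940 and 679 by 2-fold or more. XAF1 stood at 0.66 ± 0.194 CPM in the libraries labelled p53KO and 38.4 ± 11.1 in those labelled parental, and SLC17A9 at 20.2 ± 3.6 and 1.12 ± 0.41. The largest changes were ERBB4 5.35 ± 0.41, KCNE4 4.31 ± 0.24 and SLC17A9 4.20 ± 0.22 upward and AKR1B10 -6.37 ± 0.36, IFI27 -6.33 ± 0.28 and OAS2 -6.27 ± 0.18 downward. Of the interferon-stimulated genes, 0 were higher, 33 were lower and 4 did not pass (0 and 34 adjusted over the list alone). Their median was -3.87 and camera gave adjusted p = 4.2e-50. Of the MHC class I genes, 0 were higher, 15 were lower and 3 did not pass (1 and 15 adjusted over the list alone). Their median was -1.61 and camera gave adjusted p = 2.7e-12. The p53 target genes, 44 tested, were higher in the libraries labelled p53KO: 23 were higher, 3 were lower (CMBL, DRAM1, TRIM22) and 18 did not pass (24 and 4 adjusted over the list alone). Their median was 0.34 and camera gave adjusted p = 2.5e-06. Examples were GDF15 at 2.44 ± 0.16 and CDKN1A at 1.26 ± 0.09. Of the 478 genes called at 2-fold or more in 1 direction at days 3, 14 and 21, 456 (95.4%) had the opposite sign at day 0. Across the 20248 genes, which are not independent replicates, the log2 fold changes at day 0 and day 3 had Pearson r = -0.52 and Spearman rho = -0.52. Those at day 0 and day 14 had r = -0.22 and rho = -0.24, and those at day 0 and day 21 r = -0.21 and rho = -0.18.

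**Figure D4:**
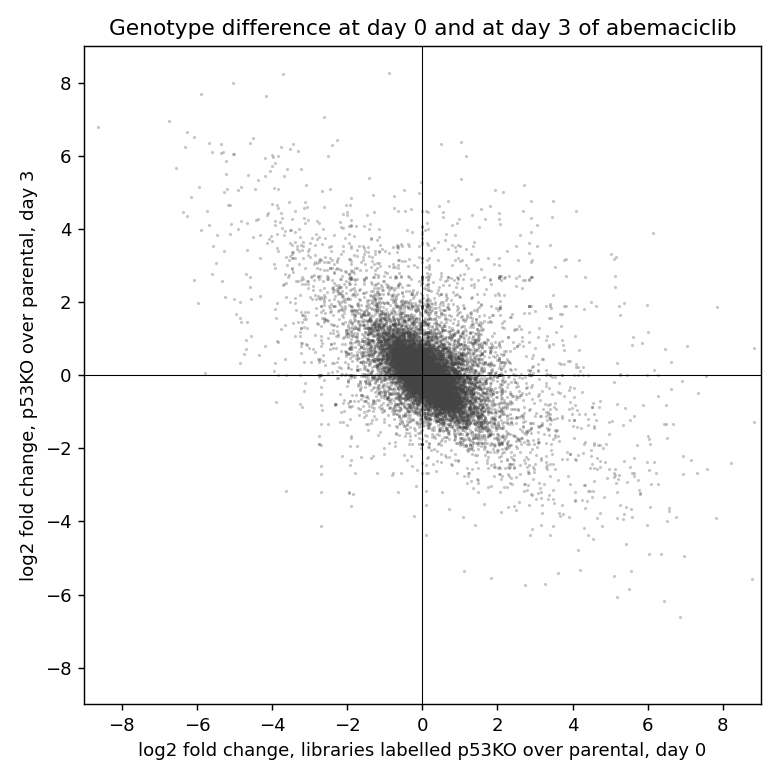
Log2 fold change of p53KO over parental for each of the 20248 genes tested, at day 0 (horizontal axis, as labelled) and at day 3 of abemaciclib (vertical axis); each point is a gene. The points run from upper left to lower right, with Pearson r = -0.52 across genes.

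Tests of whether the change from day 0 differed between the lines carry the same dependence. As labelled, 3872 genes had a higher and 3771 a lower change in p53KO at day 3, 4022 and 3687 at day 14, and 5746 and 5046 at day 21, where DESeq2 size factors gave 5130 and 5792. With the day 0 baselines exchanged the counts were 187 and 54 at day 3, 2374 and 1772 at day 14, and 5290 and 4159 at day 21. The largest differences at day 3 as labelled were XAF1 13.57 ± 0.33, OAS2 12.92 ± 0.25 and IFI27 12.57 ± 0.40 upward and AFP -10.50 ± 3.30, SLC17A9 -9.54 ± 0.33 and ERBB4 -9.29 ± 0.54 downward. Exchanging the baselines left these 6 at 1.81, 0.38, -0.08, 2.53, -1.15 and 1.41. AFP is one of the fetal liver markers, high in p53KO day 0 replicate 1 and parental day 3 replicate 2. At day 14 they were AKR1B10 12.28 ± 0.48, XAF1 11.94 ± 0.32 and OAS2 11.65 ± 0.25 and SLC17A9 -9.06 ± 0.32, ERBB4 -8.55 ± 0.53 and KCNE4 -8.00 ± 0.33, or -0.47, 0.18, -0.89, -0.67, 2.14 and 0.61 with the baselines exchanged. At day 21 they were AKR1B10 10.21 ± 0.45, XAF1 10.15 ± 0.30 and IFI27 10.07 ± 0.38 and AFP -9.83 ± 3.38, PRSS35 -8.85 ± 0.82 and IGF2 -8.82 ± 2.76, or -2.53, -1.62, -2.59, 3.21, -5.44 and 1.56 with the baselines exchanged. AFP and IGF2, of the fetal liver markers, lost their calls without p53KO day 0 replicate 1. Mitosis genes at day 14 differed with either baseline: 43 had a higher change, 0 had a lower one and 1 did not pass (43 and 0 adjusted over the list alone). Their median was 2.80 and camera gave adjusted p = 7.8e-17, or adjusted p = 0.17 with an estimated correlation. At day 3, 1 had a higher change (NDC80), 24 had a lower one and 19 did not pass (1 and 25 adjusted over the list alone). Their median was -0.97 and camera gave adjusted p = 0.0032, or adjusted p = 0.66 with an estimated correlation. At day 21, 26 had a higher change, 3 had a lower one (PLK1, CENPA, INCENP) and 15 did not pass (26 and 3 adjusted over the list alone). Their median was 1.20 and camera gave adjusted p = 0.02, or adjusted p = 0.74 with an estimated correlation. PLK1 lost its call there with the baselines exchanged, standing at -0.59, and CENPA stood at -1.65 against -2.61 ± 0.41 as labelled. Without parental day 3 replicate 2 the day 3 value was adjusted p = 0.12 (range over its alternatives 2.8e-05 to 0.66).

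Interferon-stimulated genes differed at day 3, where 36 had a higher change, 0 had a lower one and 1 did not pass (36 and 0 adjusted over the list alone). Their median was 8.65 and camera gave adjusted p = 3.5e-46. At day 14, 35 had a higher change, 0 had a lower one and 2 did not pass (35 and 0 adjusted over the list alone). Their median was 7.02 and camera gave adjusted p = 6.2e-41. At day 21, 35 had a higher change, 0 had a lower one and 2 did not pass (35 and 0 adjusted over the list alone). Their median was 6.25 and camera gave adjusted p = 4.8e-25. With the baselines exchanged the direction turned at days 14 and 21, with adjusted p = 8.7e-07 and 6.4e-05. For p53 target genes as labelled, at day 3, 5 had a higher change (FBXW7, CMBL, ASCC3, DRAM1, TRIM22), 23 had a lower one and 16 did not pass (5 and 24 adjusted over the list alone). Their median was -0.55 and camera gave adjusted p = 2.1e-06. At day 14, 4 had a higher change (FDXR, CMBL, ASCC3, TRIM22), 23 had a lower one and 17 did not pass (5 and 24 adjusted over the list alone). Their median was -0.48 and camera gave adjusted p = 7.5e-06. At day 21, 9 had a higher change, 24 had a lower one and 11 did not pass (9 and 24 adjusted over the list alone). Their median was -0.46 and camera gave adjusted p = 0.0044. With the baselines exchanged these gave adjusted p = 0.77, 0.14 and 0.94, with the direction turned at each time. Of the members named, at day 3 FBXW7 stood at 0.16 (adjusted p = 0.56), CMBL stood at -0.25 (adjusted p = 0.35), ASCC3 stood at 0.31 (adjusted p = 0.51), DRAM1 stood at 0.06 (adjusted p = 0.88) and TRIM22 stood at 2.86 (adjusted p = 0.22) in that setting. At day 14 CMBL stood at 0.11 (adjusted p = 0.59), ASCC3 stood at 0.39 (adjusted p = 0.19) and TRIM22 stood at 1.12 (adjusted p = 0.5). Of the 100 gene list calls described in these results and observations, 53 held with an estimated correlation, the ones given without such a value.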

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

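Of the tests in this part, those of the day 0, day 3, day 14 and day 21 labels, of the drug response, of a shared source in the parental libraries, of a change in the MCF7 cells and of the mitochondrial share were chosen after the result was seen, the last in place of one set beforehand. The others were set beforehand.

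The first pattern is the reversed difference between the lines at day 0: of 478 genes called at 2-fold or more in 1 direction at days 3, 14 and 21, a share of 0.954 had the opposite sign at day 0. On the premise that the knockout lowers p53 target genes, the tables argue against labels exchanged at days 3 and 14, where the list was lower in p53KO with an adjusted p of at most 0.021 with an estimated correlation, and with those labels right against an exchange at day 21, where a share of 0.212 of the 810 genes called at 2-fold or more in 1 direction at both days had the opposite sign. On the same premise they argue against a response to abemaciclib with every label right, since at day 0 the list was higher in the libraries labelled p53KO, with adjusted p = 0.00023 with an estimated correlation. Labels exchanged between the parental and p53KO libraries at day 0 may account for the pattern, a hypothesis under which the genes whose change to day 3 differed numbered 187 and 54 with the baselines exchanged, against 3872 and 3771 as labelled. The count files hold no reads for a test of the TP53 edit itself, and none of the 24 libraries is an untreated control of the later times.

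The second pattern is fetal liver and mesenchyme transcripts in 1 of the 3 replicates of 4 groups. In each such library IGF2 was the top marker, and at equal totals fewer genes had a count than in its replicates. RNA or reads of 1 other source is a candidate explanation for the p53KO pair: of 61 genes in excess in p53KO day 0 replicate 1 outside the markers, 49, a share of 0.803, were in excess in p53KO day 14 replicate 3, against 2.63% of all genes. Whether the parental libraries share that source stays open. The share was 0.574 in parental day 3 replicate 2 and 70.5% in day 14 replicate 1, against 2.69% and 3.36% of all genes. For the 61 genes median ratios to the higher other replicate were 4.9 and 9.63 (p53KO pair 13.2 and 21.2), which can lower the share. A change in the MCF7 cells stays open too: the libraries were picked by their ratio to the lowest replicate, at least 9.7. The labels do not say whether replicates were separate cultures.

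The third pattern is that parental libraries at day 21 stood apart, on the first principal component with 47.4% of the variance, and held more leukocyte and blood markers, at a mean log2 CPM of 1.21 ± 0.09 against -1.64 ± 0.13 at day 3. The larger mitochondrial share is argued against as the whole cause: it takes at most 0.09 log2 units from other genes. A share of 0.649 of these changed by more from day 3 after 2 standard errors. The test set beforehand, the count called without mitochondrial genes (13424), decides nothing as leaving out 35 genes could not move it far. A genomic DNA or unspliced RNA floor stays open for rises, but falls of 2-fold or more in 4013 genes argue against it there. A share of 0.991 of genes rising 2-fold or more lay above the 95th percentile of olfactory receptor genes, as did 0.953 of all tested. At equal totals 34 to 42 receptor genes had a count against 5 to 16 earlier in parental cells, and in p53KO 26 to 28 against 3 to 17. A change of the parental cells between day 14 and day 21, which the design names as time in the drug, may explain the pattern and stays untested against the culture or library batch, which the labels do not give.

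Other results drew attention because a test of the difference between the lines passed. The change from day 0 differed between p53KO and parental for 7643 genes at day 3, 7709 at day 14 and 10792 at day 21, and the change from day 3 to day 21 for 9309. For that last change the median log2 difference was 1.59 for estrogen receptor target genes, -2.08 for interferon-stimulated genes, 1.98 for mitosis genes, 1.06 for DNA replication and S phase genes, 1.00 for luminal epithelial genes and -1.16 for MHC class I genes. The last 4 calls ended with an estimated correlation. From day 0, interferon-stimulated genes had medians of 8.65, 7.02 and 6.25 at days 3, 14 and 21. With the day 0 baselines exchanged the direction turned at days 14 and 21. The p53 target genes had -0.55, -0.48 and -0.46, and mitosis genes -0.97, 2.80 and 1.20. With the baselines exchanged the p53 list turned and was not called at any time. The mitosis calls ended with an estimated correlation.

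Regrouping the same libraries, with only the compared libraries in each fit, gave the counts that other splits call. For each comparison of 3 against 3 libraries the 10 splits are too few for a share under 0.05. Each other split mixes the real groups, which widens the spread within it, so its low count cannot exclude chance. Between the lines the real groups called 4066 genes at day 0, 8289 at day 3, 3021 at day 14 and 15112 at day 21, and the highest other split 0 in each. Against day 0 they called 8684, 6671 and 15511 in parental cells, with a highest other of 0, and 7985, 6781 and 10363 in p53KO cells, with a highest other of 2 at day 14 and 0 at the other times. From day 3 to day 21 they called 14930 and 10094, with a highest other of 0. For the differences between the lines in a change, 50 of 200 splits were drawn, and 1, the real one, called as many. Each other split here mixes the lines within a day and cannot exclude chance either. The real counts were 8339, 5299 and 11887 from day 0 to days 3, 14 and 21 and 12252 from day 3 to day 21, and the highest others 2, 400, 8557 and 9936.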

How the results depend on the processing

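The sets without libraries with foreign transcripts or short of long ones, and with day 0 baselines exchanged, were chosen after seeing the data. The others were fixed beforehand. Of 32 counts of called genes 20 stayed within 1.5 times in every alternative run, of 106 gene list results 40 kept direction and call, and of 345 named gene results 259 did, while 24 changed direction, each of them with exchanged baselines. The direction with more called genes turned in 13 of the 16 comparisons in at least 1 alternative and in 9 with DESeq2 size factors. Neither the replicate block nor leaving out a single library moved a count of called genes by over 1.5 times. With only the groups compared the counts for p53KO against parental were 4336 higher and 3953 lower at day 3 and 1462 and 1559 at day 14, and p53KO from day 3 to day 21 had 5029 and 5065. With DESeq2 size factors TP53 stood at 140.0, 118 and 20.4 CPM in parental cells at days 0, 3 and 21. With day 0 baselines exchanged, parental cells at day 3 had 2071 genes up and 2479 down, and the difference between the lines in the change had 187 and 54 at day 3 and 2374 and 1772 at day 14. The same exchange turned the direction of interferon-stimulated genes, with adjusted p = 0.00394 and 0.0992 in parental cells at days 14 and 21, 0.182 and 0.000761 in p53KO cells, and 8.75e-07 and 6.42e-05 for the difference between the lines. It turned p53 target genes, with adjusted p = 0.756 and 0.419 in parental cells at days 14 and 21, 0.745 and 0.424 in p53KO cells at days 3 and 14, and 0.77, 0.137 and 0.945 for the difference at days 3, 14 and 21. For single genes it turned log2 fold changes, to PDZK1 0.76, EGR3 0.30, BOP1 -0.28 (parental cells at day 14), CA12 0.46, SLC39A6 0.63, KCNK5 0.74, ERBB4 1.51, PCSK9 -1.22 (p53KO cells at day 14), ERBB4 -0.26, PDZK1 0.95, FHL2 0.24 (parental cells at day 3), IFI27 -0.08, AFP 2.53, ERBB4 1.41, CMBL -0.25 (the difference between the lines at day 3), AKR1B10 -0.47, OAS2 -0.89, ERBB4 2.14, KCNE4 0.61 (the difference between the lines at day 14) and AKR1B10 -2.53, XAF1 -1.62, IFI27 -2.59, AFP 3.21, IGF2 1.56 (the difference between the lines at day 21). DNA replication and S phase genes between the lines at day 3, not called, turned without parental day 3 replicate 2 (adjusted p = 0.218; leaving out each library in turn gave 0.0562 to 0.598) and without the libraries with foreign transcripts (0.154). For these changes the cause was not tested, except that exchanged baselines compare other libraries by construction. No alternative tested a limit of depth, and at equal totals the shallowest library, parental day 14 replicate 1, held a count for 20279 genes against 25866 and 25555 in its replicates.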

Other observations

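Gene lists were fixed before the data were examined, the exchange of day 0 baselines afterwards. Cholesterol synthesis genes were lower at day 14 than at day 0 in both lines. In parental cells, of 25 such genes, 3 rose (LSS, CYP51A1, SC5D), 19 fell and 3 did not pass (3 and 20 adjusted over the list alone). Their median was -0.60 and camera gave adjusted p = 6e-06. HMGCS1, an early enzyme of the pathway, changed by -0.89 ± 0.09. In p53KO cells, 3 rose (CYP51A1, SC5D, PCSK9), 19 fell and 3 did not pass (3 and 21 adjusted over the list alone). Their median was -0.78 and camera gave adjusted p = 2.6e-08. HMGCS1 changed by -0.65 ± 0.09. Ribosome biogenesis and MYC-linked genes, 26 tested, were lower in parental cells at day 14: 2 rose (BOP1, RRP12), 20 fell and 4 did not pass (2 and 20 adjusted over the list alone). Their median was -0.58 and camera gave adjusted p = 6.7e-06. MYC stood at 0.10 ± 0.08, which did not pass. With the day 0 baselines exchanged, in parental cells LSS stood at 0.10 (adjusted p = 0.4), BOP1 stood at -0.28 (adjusted p = 0.027), RRP12 stood at 0.01 (adjusted p = 0.95) and MYC stood at 0.70 (adjusted p = 2.5e-07). In p53KO cells PCSK9 stood at -1.22 (adjusted p = 4.9e-06). Homologous recombination genes fell from day 0 in p53KO cells at day 3, where 0 rose, 19 fell and 1 did not pass (0 and 19 adjusted over the list alone). Their median was -2.30 and camera gave adjusted p = 2.8e-14. They fell at day 14, where 0 rose, 18 fell and 2 did not pass (0 and 18 adjusted over the list alone). Their median was -1.74 and camera gave adjusted p = 1.5e-09, or adjusted p = 0.065 with an estimated correlation. At day 21, 1 rose (PALB2), 18 fell and 1 did not pass (1 and 19 adjusted over the list alone). Their median was -2.49 and camera gave adjusted p = 1.4e-10, or adjusted p = 0.059 with an estimated correlation. PALB2 lost its call there with the baselines exchanged, standing at 0.01. Nuclear-encoded oxidative phosphorylation genes in p53KO cells at day 3 went down: 0 rose, 21 fell and 6 did not pass (1 and 21 adjusted over the list alone). Their median was -0.63 and camera gave adjusted p = 8.5e-06, or adjusted p = 0.37 with an estimated correlation. At day 14, 0 rose, 23 fell and 4 did not pass (0 and 23 adjusted over the list alone). Their median was -0.85 and camera gave adjusted p = 2.6e-08, or adjusted p = 0.2 with an estimated correlation. At day 21, 0 rose, 27 fell and 0 did not pass (0 and 27 adjusted over the list alone). Their median was -1.14 and camera gave adjusted p = 9.7e-10, or adjusted p = 0.16 with an estimated correlation.

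For estrogen receptor targets in parental cells at day 3, 17 rose, 4 fell (PDZK1, SIAH2, MYBL1, FHL2) and 12 did not pass (18 and 5 adjusted over the list alone). Their median was 0.35 and camera gave adjusted p = 4.8e-05. Against the other day 0 libraries PDZK1 stood at 0.95 (adjusted p = 1.2e-08), SIAH2 stood at -0.15 (adjusted p = 0.26) and FHL2 stood at 0.24 (adjusted p = 0.46). At day 21, 11 rose, 22 fell and 0 did not pass (11 and 22 adjusted over the list alone). Their median was -0.89 and camera gave adjusted p = 0.021, or adjusted p = 0.12 with an estimated correlation. In p53KO cells at day 3, 16 rose, 9 fell and 8 did not pass (16 and 9 adjusted over the list alone). Their median was 0.32 and camera gave adjusted p = 0.092, which did not pass, and with the baselines exchanged adjusted p = 6.5e-05 (range over its alternatives 6.5e-05 to 0.29). At day 21, 21 rose, 6 fell and 6 did not pass (22 and 6 adjusted over the list alone). Their median was 0.57 and camera gave adjusted p = 0.00066. Between the libraries labelled p53KO and parental at day 0, of mitochondrially encoded genes 13 were higher, 0 were lower and 0 did not pass (13 and 0 adjusted over the list alone). Their median was 0.73 and camera gave adjusted p = 3.7e-10, or adjusted p = 0.059 with an estimated correlation. Of lysosome and autophagy genes there, 23 were higher, 3 were lower (ATP6V1A, UVRAG, LIPA) and 15 did not pass (25 and 3 adjusted over the list alone). Their median was 0.37 and camera gave adjusted p = 9.3e-07, or adjusted p = 0.059 with an estimated correlation.

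Over the 16 contrasts, camera with the preset correlation called the remaining lists as follows: replication-dependent histone genes (12 tested) 1 up and 1 down, lowest adjusted p = 0.035, basal and mesenchymal genes (22 tested) 1 up and 0 down, lowest adjusted p = 0.012, hypoxia and glycolysis genes (23 tested) 0 up and 0 down, lowest adjusted p = 0.085, unfolded protein and ATF4 response genes (25 tested) 0 up and 4 down, lowest adjusted p = 0.00029, AP-1 and immediate early genes (21 tested) 0 up and 0 down, lowest adjusted p = 0.052. For the others it called BCL2 family and caspase genes (22 tested) 1 up and 0 down, lowest adjusted p = 0.023, fibroblast markers (9 tested) 0 up and 0 down, lowest adjusted p = 0.25, leukocyte and blood markers (7 tested) 1 up and 0 down, lowest adjusted p = 0.046, endothelial markers (5 tested) 0 up and 0 down, lowest adjusted p = 0.29, reference genes (12 tested) 0 up and 0 down, lowest adjusted p = 0.073. The leukocyte and blood call was for parental cells from day 3 to day 21. None of these calls held with an estimated correlation.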
